A study of Caenorhabditis elegans with 4 samples.

How the data were processed

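Total RNA from early embryos, prepared by bleaching gravid adults grown in liquid culture and extracted with Trizol and RNeasy columns, was labelled with Cy3 by NimbleGen, per the labels' protocols. There were 4 samples in 1 group, replicates 1 to 4 of the labels, written as arrays 1 to 4. The labels name the strain as the hpl-2 mutant PFR40, while the growth protocol names N2 adults, and this conflict could not be settled from the sources used here. The wild-type arrays named in the design text were not analysed here.

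The values were linear microarray intensity values, quantile normalized and averaged to 1 value per transcript by the authors, per the file headers and the naming of the deposited files. The 4 arrays had near-equal quartiles, with upper quartiles of 5748 to 5805. The scanner, the background correction, the genome build and the number of probes averaged per transcript are not given in the sources used here. A table of the whole series held the same values as the tables of single samples, with a largest difference of 0. Quantile normalization forces the arrays onto 1 distribution, so a shift of most transcripts between arrays could not be seen, and averaging probes can hide disagreement between the parts of a transcript.

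Transcript names were matched to a RefSeq gene table of assembly WBcel235, used only for gene names, chromosomes and the position of genes along them. Of 23181 transcripts, 17151 matched as written, 5352 after removal of the isoform letter, and 678 stayed unmatched. They gave 19380 named genes, of which 2179 had several transcripts. In 185 of these, some transcripts were above background and others were not. Of the members of the 22 gene lists, 5 were not found under their written symbols (vet-4, opt-2, elt-5, unc-17 and daf-21) and were not used. The 22 gene lists, the tests of the report and their alternatives were fixed before the data were examined. The second gene lists, the tests of explanations and the count of highly variable transcripts were added after that.

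Values were taken as log2 after raising any below 1 to 1. The background of each array was the 95th percentile of the log2 signal over 1326 chemoreceptor genes, which came to 8.10, 8.45, 8.28 and 8.48 on arrays 1 to 4. Log2 signal minus that background was fitted with limma 3.58.1 (lmFit and eBayes, intercept only, R 4.3.3) and tested against 0, two-sided, with Benjamini-Hochberg adjustment at 0.05 over all transcripts. The difference of the background between arrays enters the spread of every transcript in the fit. For set-25, for example, the SD was 0.024 for the log2 signal and 0.19 above background, and for chs-1 0.78 and 0.62. An error of the background that all arrays share is left out of the fit. Values above background are given on this log2 scale, which depends on each probe's own brightness, so levels of different genes were not ranked. A gene took the values of its transcript with the highest mean and counted as above background if any of its transcripts did. On simulated data, 200 transcripts set to 0.25, 0.5 or 1 log2 above background in a fit of 23181 were called above in 68.5%, 91% and 97.5% of cases. With no true difference, 1.5% were called above and 2% below. The simulated noise was independent between transcripts, whereas a background shift moves all transcripts of an array together. These rates therefore do not cover errors shared between transcripts.

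Gene lists and chromosomes were compared with the other named genes by Fisher's exact test, two-sided, with the chemoreceptors left out and Benjamini-Hochberg adjustment over 21 lists or 6 chromosomes. Autosomes were also divided into 3 equal parts of their annotated gene span. For differences between arrays, the median over the members of a list above background of the log2 deviation from the mean of the 4 arrays was set against 10000 random lists of the same size, drawn with replacement within 10 classes of mean signal. A list was called on an array if it lay outside the central 95%. As a check of this step, 200 random lists of 15 transcripts were drawn from the real deviations. Of these, 6.5% lay outside that range on array 1, and 100% did after 0.3 was added to their medians. Such lists come from the same transcripts as the random lists they were set against, so the first share is nearly set by construction. It does not give the rate of false calls for lists of genes that vary together. Agreement of the arrays was described by Pearson's r, Spearman's rho, the SD per transcript and a principal component analysis, with no test.

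Genes named in the text were chosen by a rule set beforehand: every measured member of the heterochromatin list, the first 3 measured members of each other list, up to 2 more members whose call was the opposite of the list's majority, and the 10 genes above background with the largest SD. Alternatives were the 99th and 75th percentile of the chemoreceptors, the 25th percentile of all genes, each replicate left out, the series table, median centring, a mean-variance trend, the mean of a gene's transcripts and a rule with no model. For the differences between arrays they were all measured members, means, unmatched random lists, quantile normalization repeated, and transcripts above background alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.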

Results

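The series profiled total RNA from early embryos of the nematode Caenorhabditis elegans on 4 single-colour NimbleGen arrays. All 4 arrays form 1 group, labelled as strain PFR40, which carries the allele tm1489 of hpl-2. The gene hpl-2 encodes a heterochromatin protein 1 homolog, a reader of methylated lysine 9 on histone H3. The design text set these arrays against 4 wild-type arrays of another series, and those arrays were not analysed here. The results therefore describe which genes gave signal in the embryos labelled mutant and how far the 4 arrays differed, and hold no mutant against wild-type difference. The growth protocol of the same samples names N2, the wild-type strain, as the source of the embryos, while the genotype labels name the mutant. The labels also mention a small share of males among the hermaphrodites. Each array gave a linear normalized signal for 23181 transcripts, with a median between 576 and 591. The number of arrays limits the precision. The labels do not say whether the replicates came from separate cultures. The limma p-values therefore measure only the spread between these samples and their backgrounds, which may be technical. Those of Fisher's exact test take genes as units and hold no spread between samples. Genes that vary together are not independent units, so these p-values describe the lists and chromosomes on these arrays only.

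The transcripts of hpl-2 itself gave signal on every array. Its 3 transcripts, on chromosome III, had mean signals of 2477 ± 77.8 for K01G5.2a, 1521 ± 78.1 for K01G5.2b and 1450 ± 65.5 for K01G5.2c (SD, n = 4). On the log2 scale K01G5.2a lay 2.95 ± 0.14 above the background of the arrays (SD, n = 4), with a limma adjusted p of 7.75e-09. The background of an array was the 95th percentile of its signal over chemoreceptor genes, which are families of receptors used by neurons. The positions of the probes relative to the tm1489 deletion were not given in the sources used here, so this signal does not check the genotype label.

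Genes of the heterochromatin pathway were above background without exception. All 12 measured members passed, against 55.4% of the other named genes (Fisher's exact test, two-sided, adjusted p = 0.00178). The paralog hpl-1 lay 4.36 ± 0.21 above background on the log2 scale, and the H3K9 methyltransferases met-2 and set-25 lay 4.90 ± 0.18 and 5.61 ± 0.19 above it (SD, n = 4). The zinc finger gene lin-13 lay 6.52 above background, lin-61 4.90, cec-4 5.86, lin-65 5.49, arle-14 5.52, set-26 6.45, lem-2 4.56 and set-32 3.13. All 13 synMuv B and DREAM genes, the transcriptional repressors with which hpl-2 is grouped genetically, were above background as well (adjusted p = 0.00178). Among them the retinoblastoma homolog lin-35 lay 5.40 above background and efl-1, an E2F factor, 5.63. All 8 genes of the list for PRC2 and H3K36 methylation passed (adjusted p = 0.0147), with mes-4 at 5.77 and mes-2 at 4.35 above background. Its members set-2 and spr-5 belong to neither group, and PRC2 and H3K36 is used below only as the name of the list. With the lower background of the 75th percentile of the chemoreceptors, 74.1% of the other genes were also above it. The lists still had all members above, but the exact test gave adjusted p = 0.0722 for heterochromatin, 0.0585 for synMuv B and DREAM and 0.151 for PRC2 and H3K36. The last list also missed the threshold with the 25th percentile of all genes as background (adjusted p = 0.143).

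Across the genome, 10053 of 19380 named genes (51.9%) gave signal above background. Of the 23181 transcripts, 12755 were above background, 8402 were below it and 2024 could not be told apart from it. Of the chemoreceptor genes themselves, 42 of 1326 were above, among them sra-33 and srab-23, while sra-1, sra-2 and sra-3 were below. The counts rest on where the background is set. The genes above it numbered 8513 with the 99th percentile of the chemoreceptors and 13579 with the 75th.

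Maternal, germline and cell division genes gave signal almost throughout. All 22 maternal regulators of cell fate were above background (exact test, adjusted p = 1.48e-05), including the RNA-binding protein gene mex-3 at 6.22 log2 above it, pie-1 at 4.85 and skn-1 at 5.58. So were all 22 genes of mitosis and replication (adjusted p = 1.48e-05), with cdk-1 at 6.07, the Aurora B kinase gene air-2 at 5.62 and the replication helicase gene mcm-2 at 6.28. The 12 P granule genes, which encode proteins of germ granules, and the 15 genes of meiotic chromosomes all passed (adjusted p = 0.00178 and 0.000872). With the 75th percentile as background the P granule list gave adjusted p = 0.0722. Here pgl-1 lay 5.77 above background, glh-1 4.86 and the meiotic axis gene him-3 4.30. All 21 small RNA pathway genes passed (adjusted p = 2.22e-05), among them the Argonaute genes csr-1 at 3.87, hrde-1 at 5.88 and prg-1 at 5.75. Of the eggshell genes 9 of 11 were above background, a share that did not pass the test against the other genes (adjusted p = 0.147). The chitin synthase gene chs-1 lay 3.04 above background, cbd-1 6.15 and egg-1 4.39, whereas perm-2 lay at -0.37 and was called below, and perm-4 at -0.08 was not told apart. The perm-2 call was lost without array 2, 3 or 4, when its values were -0.28, -0.42 and -0.24. With the 99th percentile as background the eggshell list passed, with 9 of 11 members and adjusted p = 0.043.

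Zygotic regulators and several tissue lists were also present. Of 22 early zygotic genes, 18 were above background (adjusted p = 0.0215), including the endoderm factor end-1 at 3.03 log2, the T-box gene tbx-37 at 3.41 and pes-10 at 4.50. The near-identical pair med-1 and med-2 lay at -0.01 and -0.11 and were not told apart from background. Signal shared between such copies cannot be split here. The early zygotic call was lost with the other 3 backgrounds tried (adjusted p from 0.0561 to 0.170). All 14 muscle genes passed (adjusted p = 0.00144), with the myogenic factor hlh-1 at 4.68 above background and the myosin genes myo-3 and unc-54 at 2.36 and 3.34. All 10 epidermis genes passed (adjusted p = 0.00493), with lin-26 at 6.03, elt-1 at 5.84 and nhr-25 at 5.06. With the 75th percentile as background the exact test gave adjusted p = 0.0585 for muscle and 0.108 for epidermis, and with the 25th percentile of all genes 0.0577 for epidermis. Both lists were higher on array 1 than on the others, by the deviations given with the array differences.

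Lists of later differentiation held members on both sides of the background, and none of these shares passed the test against the other genes. The counts above background were 7 of 10 for endoderm (adjusted p = 0.554), 5 of 9 for pharynx (adjusted p = 1), 13 of 19 for neurons (adjusted p = 0.394) and 7 of 19 for cuticle (adjusted p = 0.138). In the endoderm list the intestinal factor elt-2 lay 3.97 above background and the esterase gene ges-1 1.47, while the proteases asp-1 and cpr-1 lay at -0.29 and -0.85, the second of them called below. In the pharynx list the organ selector pha-4 lay 4.91 above background and ceh-22 1.83, while the pharyngeal myosin genes myo-2 and myo-1 were below at -0.36 and -0.68, as was the troponin gene tnc-2 at -0.71. The myo-2 call was lost without array 4 (-0.26). In the neuron list unc-119 and unc-86 lay 3.84 and 3.48 above background, rab-3 at -0.29 was not told apart from it, and the synaptotagmin gene snt-1 was below at -0.59. Without array 1, rab-3 and asp-1 were called below, at -0.57 and -0.56. Among the cuticle genes the collagens dpy-7, sqt-3, dpy-17 and dpy-2 lay 4.70, 5.28, 5.88 and 3.04 above background, and rol-6 was below at -0.75. Without array 2 the cuticle list had 6 of 19 members above, fewer than the other genes (adjusted p = 0.0480). With the 75th percentile as background all 19 neuron genes were above it (adjusted p = 0.0225).

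Markers of adult tissue moved apart. None of the 6 vitellogenin genes, which encode the yolk proteins made in the adult intestine, was above background, and all 6 were called below it (exact test, adjusted p = 0.0117). The values for vit-2, vit-5 and vit-6 were -0.34, -0.28 and -0.67 on the log2 scale. The calls of vit-2 and vit-5 were lost without array 2 (-0.29 and -0.22) and without array 4 (-0.29 and -0.23), the arrays with the highest backgrounds. The log2 signals themselves varied little, with SDs of 0.015 for vit-2 and 0.084 for vit-5 (n = 4). No array shows that the vitellogenin probes respond, so the low values do not show that adult tissue was absent. Genes of a family are also not independent units. The vitellogenin call depended on the background, since 5 of the 6 were above it at the 75th percentile of the chemoreceptors and 4 of the 6 at the 25th percentile of all genes (adjusted p = 1 for both). Of the sperm genes, 36 of 38 were above background (adjusted p = 1.71e-06). The major sperm protein genes msp-3, msp-10 and msp-19 lay 0.41, 2.53 and 2.24 above it, spe-11 at 0.03 was not told apart from it, and spe-38 at -0.89 was below. Members of the major sperm protein family are close copies, so their signals are not independent.

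Ribosomal protein, dosage compensation and heat shock genes were above background with few exceptions. The count was 61 of 62 for ribosomal proteins (adjusted p = 1.98e-13), with rpl-3, rpl-4 and rpl-5 at 6.15, 6.52 and 6.53, and rpl-42 the exception at -0.55, called below. Dosage compensation and sex determination had 15 of 16 (adjusted p = 0.0028), with sdc-2 at 4.74, dpy-27 at 6.08 and xol-1 at 2.27. The masculinizing gene her-1, at 0.30, was not told apart from background with all 4 arrays, and was called above it without array 1 (0.22) or array 3 (0.43). All 12 heat shock genes passed (adjusted p = 0.00178), among them hsp-1 at 6.82, hsp-16.2 at 3.91 and hsp-70 at 1.98. With the 75th percentile as background the heat shock list gave adjusted p = 0.0722. Adjusted over the list alone, each of the 21 lists gave the same count of members above background as adjusted over all transcripts.

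**Figure D1:**
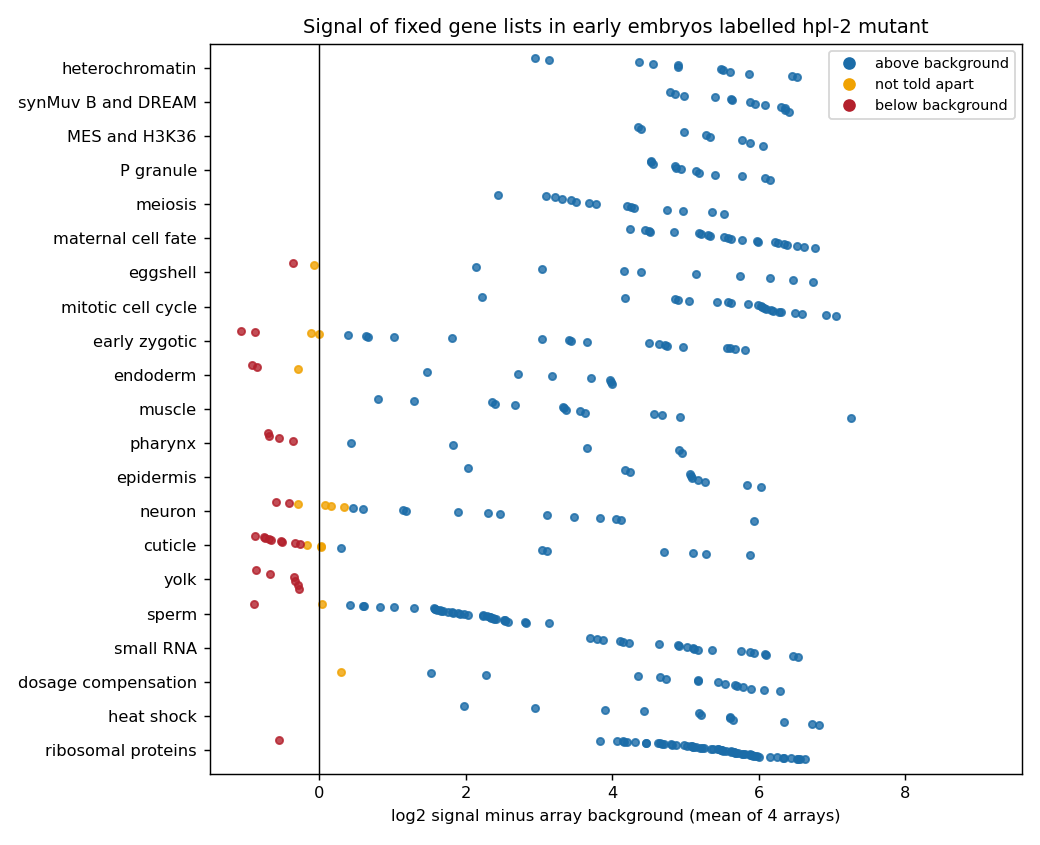
Signal of each measured member of the 21 fixed gene lists, as log2 signal minus array background averaged over the 4 arrays (horizontal axis). Colours give the limma call, and all 6 yolk genes lie left of 0 while all 12 heterochromatin genes lie right of 2.9.

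Chromosomes differed in the share of genes above background. Chromosome III had 69.3% of its genes above, chromosome I 67.8% and chromosome II 58.0% (adjusted p = 1.17e-52, 1.87e-45 and 0.00208, Fisher's exact test, two-sided, against the genes of the other chromosomes). The X chromosome had 1306 of 2613 genes above, against 56.4% of the other genes (adjusted p = 2.19e-09), and chromosome V had 40.5%, against 59.6% (adjusted p = 1.70e-100). Chromosome IV, with 54.3%, did not pass the test (adjusted p = 0.172), and passed it with the 75th percentile as background (72.5% against 74.4%, adjusted p = 0.0341). The X chromosome is known to be largely silent in the germline, and the outer parts of the autosomes carry most of the H3K9 methylation. With each autosome divided into 3 equal parts, 55.4% of the genes in the outer parts were above background and 57.9% in the middle part (p = 0.00222, exact). That difference changed direction with the 75th percentile of the chemoreceptors (74.7% outer, 73.9% middle, Fisher's exact test, p = 0.241) and with the 25th percentile of all genes (70.7% in both, p = 0.971). The chromosome II call ended with the 99th percentile (48.7% against 46.8%, adjusted p = 0.0537). Chemoreceptor genes were left out of these shares, and neighbouring genes and gene families are not independent units.

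The arrays agreed closely across transcripts but differed in defined gene groups, with array 1 farthest from the rest. Pearson's r between arrays was 0.981 to 0.996 and Spearman's rho 0.970 to 0.990, across transcripts, which are not independent replicates. The lowest values of both belonged to the pair of arrays 1 and 2. The median SD over the arrays was 0.12 on the log2 scale, and 0.08 without array 1. The leading component held 75.9% of the variance between arrays, with scores of 0.80, -0.52, 0.0026 and -0.28 for arrays 1 to 4. It held 86.6% without array 3, 67.1% being the lowest value with 1 array left out.

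Muscle and cuticle genes were highest on array 1. The median member of the muscle list that was above background deviated by 0.94 log2 from the mean of the 4 arrays on array 1, by -0.63 on array 2, 0.08 on array 3 and -0.44 on array 4. For myo-3 the log2 signals on arrays 1 to 4 were 12.08, 9.52, 10.90 and 10.24, a 5.88-fold range, and for unc-54 they were 12.98, 10.60, 11.94 and 11.13. The 7 of 19 cuticle genes above background deviated by 0.74, -0.45, 0.0076 and -0.23 in the same order, with dpy-7 spanning a 2.78-fold range and dpy-2 a 3.90-fold range. Over all 19 measured cuticle genes the medians were closer to 0 on arrays 1 and 2, at 0.11 and 0.0091. Pharynx, endoderm, epidermis and neuron genes were also higher on array 1, by 0.38, 0.28, 0.28 and 0.24, and ribosomal proteins by 0.10. Each of these deviations on array 1 lay above the central 95% of 10000 random lists matched on signal, which describes these arrays and tests no condition. Without array 1, muscle genes still lay higher on array 3 than on array 2, by deviations of 0.41 and -0.33. On array 4 they then lay at -0.017, inside the central 95% (percentile 12.7).

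Oocyte, germline and heat shock genes ran the other way on array 1. The eggshell list deviated by -0.55 there and by 0.08, 0.15 and 0.31 on arrays 2 to 4. The chitin synthase gene chs-1 had log2 signals of 10.24, 11.58, 11.59 and 12.04, a 3.48-fold range. Meiosis genes deviated by -0.41 on array 1, P granule genes by -0.15, and maternal cell fate genes by -0.098, all below the central 95% of the matched random lists. Against random lists not matched on signal, the P granule and maternal lists lay inside that range (percentiles 5.91 and 16.7), and the maternal list also did when means replaced medians (percentile 3.87). The heat shock list deviated by -0.39 on array 1 and 0.32 on array 4. The inducible genes hsp-70 and hsp-16.2 spanned 6.79-fold and 3.52-fold ranges, lowest on array 1 and highest on array 4, while hsp-1 spanned 1.04-fold. Sperm genes deviated by -0.56, 0.48, 0.15 and -0.06, and early zygotic genes by -0.12, 0.10, 0.03 and 0.03. Of these last only array 2 lay outside the central 95%, with array 1 at percentile 7.83, or 2.25 over all measured members. The heterochromatin, synMuv B and DREAM, PRC2 and H3K36, mitotic, small RNA and dosage compensation lists stayed inside the central 95% of random lists on all 4 arrays, although dosage compensation genes lay outside it on array 2 without array 1 (0.034), and small RNA genes then did on array 4 (-0.021). On array 1 their medians were -0.0027, -0.011, -0.041, -0.024, -0.050 and -0.021. Of the 20 lists, 13 lay outside that range on array 1, 12 on array 2, 11 on array 3 and 10 on array 4. On array 3 the number was 5 without array 1.

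**Figure D2:**
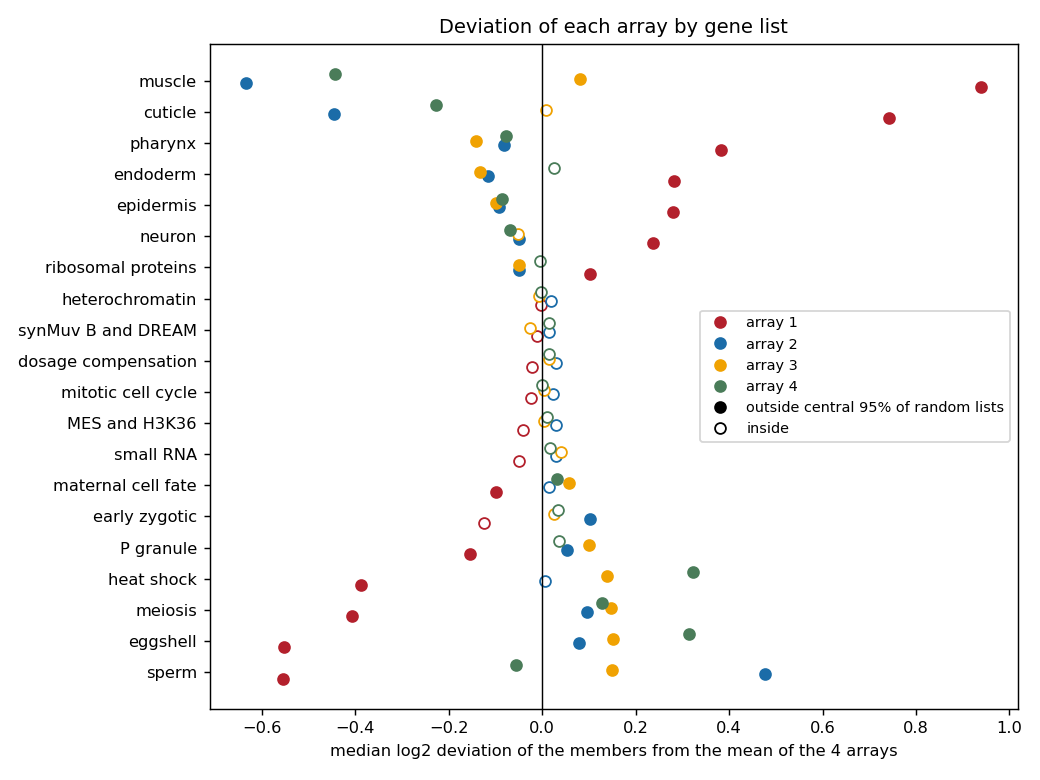
Median log2 deviation of each gene list from the mean of the 4 arrays (horizontal axis), 1 point per array, over members above background. Filled points lie outside the central 95% of random lists matched on signal, and muscle genes span -0.63 on array 2 to 0.94 on array 1.

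The 10 genes with the largest SD over the arrays, among those above background, were lpr-4, far-1, F30H5.3, chtb-1, T03G6.1, lpr-5, F44E2.4, alp-1, Y50D4C.2 and hum-6. The lipocalin-related gene lpr-4 had log2 signals of 12.89, 8.73, 11.74 and 9.99 on arrays 1 to 4, a 17.8-fold range. The fatty acid and retinol binding protein gene far-1 had 13.62, 10.04, 12.72 and 10.90, an 11.9-fold range. All but Y50D4C.2 were highest on array 1, next on array 3 and lowest on array 2. With the 99th percentile as background, lpr-4, F30H5.3, T03G6.1, alp-1 and Y50D4C.2 were no longer called above it (adjusted p from 0.0597 to 0.290). The calls of F30H5.3 and alp-1 were also lost without array 3 (adjusted p = 0.0937 and 0.0590).

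**Figure D3:**
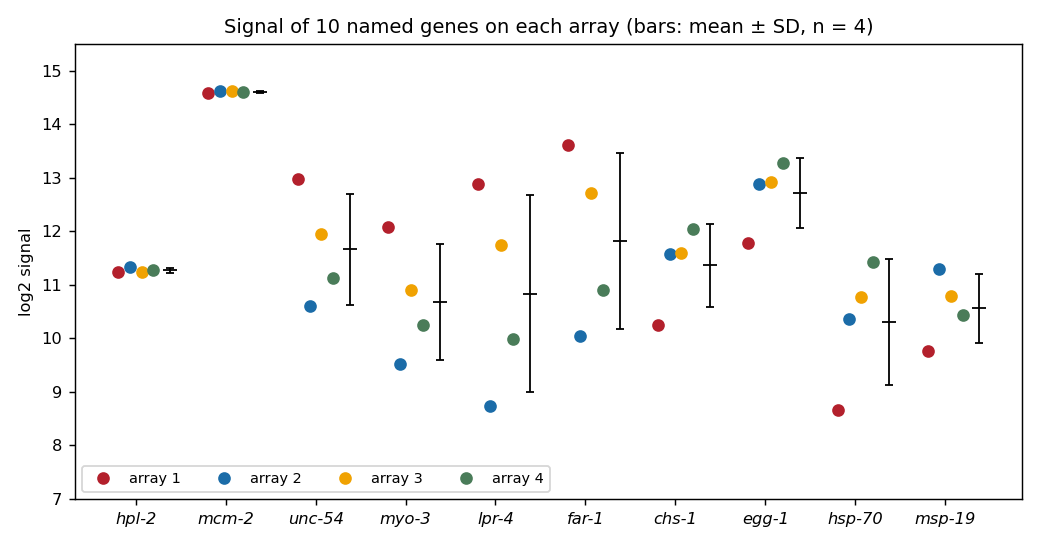
The log2 signal (vertical axis) of 10 named genes on each of the 4 arrays, with the mean and SD (n = 4) as a bar to the right of each gene. The points of hpl-2 and mcm-2 nearly coincide, while those of lpr-4 run from 8.73 on array 2 to 12.89 on array 1.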

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

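Of the tests in this part, the one on a second set of tissue and oocyte genes was written before its result was seen, and those on the signal scale and on adults were chosen after the result was seen. Single arrays stood apart from the other 3 by more than Dixon's limit for 4 samples in 4 of 103 named genes and in 5 of 20 lists. Chance alone gives about 1 in 20, so the count of genes shows no excess over chance and only the count of lists does. The lists are not independent of each other.

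Array 1 was the array apart in all 4 genes and in 4 of the 5 lists. The log2 signal of set-32, a predicted histone methyltransferase gene, was 11.09 on array 1 and 11.57 to 11.59 on the others. The germ granule gene pgl-3 had 12.22 against 12.999 to 13.14, and the meiotic axis gene him-3 had 12.14 against 12.75 to 12.81. The gene Y50D4C.2 had 12.05 on array 1 against 9.34 to 9.62, and is also 1 of the 44 transcripts that rose on a single array, so it need not share a source with the others. Meiosis genes deviated by -0.41 on array 1, and pharynx, epidermis and neuron genes by 0.38, 0.28 and 0.24. In the heterochromatin list the array apart was array 2, at 0.018 against -0.0060 to -0.0024, a gap far smaller than the others.

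Higher tissue genes and lower oocyte and meiosis genes on array 1 could come from older embryos in that preparation. In a second set of genes, none of them in the lists of the report, muscle, epidermis and oocyte genes deviated by 0.81, 0.46 and -0.23 on array 1. The first groups together minus the last came to 0.74 (bootstrap over genes 0.59 to 1.11), the direction that older embryos predict. The interval covers the choice of genes on 1 array and not the spread between preparations. Any cause that moves these tissues alike would give the same direction, so the result does not single out age. A distortion of the signal scale is argued against, since the second muscle genes lay at percentile 100 among lists of the same signal. Gravid adults carried over were predicted to raise the second oocyte genes, which lay at -0.23. That test cannot decide, since whole adults add somatic as well as germline RNA to embryos that already hold maternal RNA. On arrays 2 to 4 the second muscle genes lay at -0.54, -0.019 and -0.27 and the second oocyte genes at 0.050, 0.11 and 0.076. Both ran in the order 3, 4, 2 from high to low, where an age difference would reverse 1 of them. The oocyte gaps are small and carry no estimate of spread. In the first lists, eggshell genes (0.08, 0.15 and 0.31) ran against muscle genes (-0.63, 0.08 and -0.44) between arrays 3 and 4 but in neither other pair. These values neither show nor exclude that age alone accounts for arrays 2 to 4. Gravid adults carried over, a different mix of tissues at 1 age and a handling difference between preparations stay open. The labels give 1 age and no other difference, so no biological explanation named by the design was tested.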

How the results depend on the processing

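Moving the background changed more calls of transcripts above it than any other choice did. For lists on single arrays, leaving out replicate 1 changed most, with 15 values reversed in sign after lying outside the central 95%. The genes above background numbered 8513 to 13579 over all alternatives, and 9777 to 10144 with 1 replicate left out. All 12755 transcripts above background remained so with the 75th percentile of the chemoreceptors and the 25th percentile of all genes, and 10878 of them with the 99th percentile. These backgrounds are lower or higher on every array, which nests the calls nearly by construction, so the overlap says little about stability. The transcripts below background dropped from 8402 to 3027 and 4314 with those lower backgrounds. Median centring and the series table moved nothing by construction and say nothing about stability. No paired analysis was possible because there was 1 group. Signal over background limits what can be called: at 0.25 log2 above it, 68.5% of transcripts simulated with independent noise were called. Counts of genes with signal near the background are therefore the least certain. The cause was not tested where none is given.

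With the 75th percentile of the chemoreceptors, the members above were 12 for heterochromatin, 13 for synMuv B and DREAM, 8 for PRC2 and H3K36, 12 for P granules, 20 for early zygotic genes, 14 for muscle, 10 for epidermis and 12 for heat shock. All of these then missed the threshold, with 74.1% of the other genes also above. The lists with every member above could rise no further, and the early zygotic list, with 20 of 22, was not among those. Neuron genes, with 19, then passed it, and yolk, with 5 of 6, turned from below to above the share of other genes. With the 25th percentile of all genes, PRC2 and H3K36 with 8, early zygotic genes with 20, epidermis with 10 and yolk with 4 missed it. With the 99th percentile, eggshell genes with 9 passed and early zygotic genes with 14 missed it. Chromosome II then had 48.7% above and missed it, and chromosome IV had 72.5% and passed it with the 75th percentile. The outer parts of the autosomes turned to the higher share, 74.7% with the 75th percentile and 70.7% with the 25th percentile of all genes. Cuticle members above were 6 to 7 with 1 replicate left out, and passed the threshold without replicate 2.

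Among the named genes called above or below background, the sign changed only where the background was moved, which is how those alternatives are built. With the 75th percentile the called genes that changed sign were perm-2 at 0.47, myo-2 at 0.48, myo-1 at 0.16, tnc-2 at 0.13, snt-1 at 0.25, rol-6 at 0.090, vit-2 at 0.50, vit-5 at 0.56, vit-6 at 0.17 and rpl-42 at 0.29. With the 25th percentile of all genes they were perm-2 at 0.35, myo-2 at 0.36, myo-1 at 0.033, tnc-2 at 0.0089, snt-1 at 0.13, vit-2 at 0.38, vit-5 at 0.44, vit-6 at 0.043 and rpl-42 at 0.17. With the 99th percentile they were msp-3 at -0.50 and srab-23 at -0.51. Each of the 8 named genes not told apart from background changed sign under at least 1 moved background. With 1 replicate left out, perm-4, med-1 and spe-11 did so (-0.16 to 0.021, -0.044 to 0.017 and -0.062 to 0.17), and unc-25 did with the mean of its transcripts (-0.028). Without those settings that move nothing, 961 comparisons of named genes kept the call, and of these 953 kept the sign and 8 changed it, all in genes not told apart from background. Another 22 lost the call, 16 gained it, and 10 gained it with the other sign.

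Between the arrays, mean Pearson's r was 0.981 and the leading component 84.9% over transcripts above background alone. With 1 replicate left out, the median SD was 0.079 to 0.12, the component 67.1% to 86.6%, and the lists outside the central 95% on array 3 numbered 5 to 12. The transcripts above background with SD over 1, a count chosen after seeing the data, numbered 72, 70 after repeated quantile normalization, and 13 to 167 with 1 replicate left out. Over all measured members, cuticle genes on array 2 turned to 0.0091. With 1 replicate left out the mean of the arrays moves, so lists near it can change sign by construction. Those outside the central 95% with all 4 arrays that did so were P granule genes on array 2 (-0.011 to 0.080), meiosis on array 2 (-0.027 to 0.16), maternal genes on array 4 (-0.0055 to 0.053), eggshell on array 2 (-0.037 to 0.16) and array 3 (-0.053 to 0.28), and endoderm on array 3 (-0.23 to 0.022). They were also muscle on array 3 (-0.10 to 0.41), pharynx on array 2 (-0.16 to 0.047) and array 4 (-0.15 to 0.050), epidermis on array 3 (-0.14 to 0.011) and array 4 (-0.12 to 0.014), and neurons on array 2 (-0.10 to 0.013) and array 4 (-0.11 to 0.012). The remaining ones were cuticle on array 4 (-0.40 to 0.0080), sperm on array 3 (-0.060 to 0.29) and array 4 (-0.23 to 0.10), and heat shock on array 3 (-0.0043 to 0.23). Lists inside the central 95% with all 4 arrays also changed sign. Of these, small RNA genes on array 4 (-0.021), maternal genes on array 2 (-0.026), early zygotic genes on arrays 3 and 4 (-0.046 and -0.027), heat shock on array 2 (-0.14) and ribosomal proteins on array 4 (0.021) then lay outside it without replicate 1. Cuticle genes on array 3 did so without replicate 2 and without replicate 4 (-0.14 and -0.085). Of all such comparisons, 410 kept the call with little shift, of which 389 kept the sign and 21 changed it, 22 lost the call and 12 gained it with the same sign. Another 17 shifted by more than the spread or gained the call with the other sign.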

Other observations

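The tests in this part on variable transcripts, their recounts with an array left out, and those on sperm genes, vitellogenins and embryo age were chosen after the result was seen, and the one on other transcripts of the same gene before. Over the 4 arrays, 72 transcripts of 56 genes above background had an SD over 1 on the log2 scale. Of these transcripts, 65 (90.3%) were highest on array 1, next on array 3, then array 4 and lowest on array 2. The scores of the leading component run in the same order. Picking transcripts by a large SD favours that component, and several share a gene, so the 4.17% of equally frequent orders is no fair comparison. The muscle list held 5 of the 56 genes out of its 14 members above background, namely lev-11, mup-2, myo-3, unc-15 and unc-54, which encode thick and thin filament proteins. Elsewhere 0.510% of genes above background varied as much (Fisher's exact test, two-sided, adjusted p = 1.76e-07 over 20 lists). The count was chosen after the data were seen, and all 5 muscle genes ran in the array order given above. They are therefore not independent, and this p-value restates the muscle difference between arrays and is no separate support for it. The cuticle list held dpy-3 and the heat shock list hsp-70 (adjusted p = 0.385 and 0.434), and the other 17 lists held none. The count of 72 depended on which arrays entered, with 13 transcripts without array 1, 167 without array 3 and 134 without array 4.

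Some fixed lists had most members above background highest or lowest on 1 array, and others did not, a count without a test. The synMuv B and DREAM list had 4, 3, 3 and 3 members highest on arrays 1 to 4, and of the 22 mitotic genes 10 were lowest on array 1. All 15 meiosis genes and all 12 P granule genes were lowest on array 1. Of the 61 ribosomal protein genes above background, 54 were highest on array 1. Of the 9 eggshell genes above background, 8 were lowest on array 1 and 8 were highest on array 4. The inducible heat shock gene hsp-70 had log2 signals of 8.66, 10.37, 10.77 and 11.42 on arrays 1 to 4.

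Sperm genes varied in another order, with all 36 members above background lowest on array 1 and 33 highest on array 2. All 30 major sperm protein genes were higher on array 2 than on array 1, by a median of 1.01 log2. Signal shared between the copies of that family is argued against as the whole source, since the 6 other sperm genes above background were also higher on array 2, by a median of 1.01 (0.37 to 1.69). Adult hermaphrodite tissue carried over cannot be told apart, because the highest vitellogenin lay at -0.38 against the background of array 2 but no array shows that these probes respond. Males or sperm in the preparation, which the labels mention in small number, and embryo age may also contribute and were not tested.

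In 44 transcripts a single array exceeded the highest of the other 3 by at least 2 log2 while those lay within 1 of each other, and in 0 transcripts did an array fall below the others in that way. The rises fell on all arrays, 12, 18, 5 and 9 on arrays 1 to 4, and 3 of the transcripts were called above background. For example clc-10 had 14.20 on array 1 against at most 7.92 on the others, and col-90 had 12.92 on array 4 against at most 7.97, both chosen after their values were seen. Older embryos on array 1 would not account for the rises on the other arrays, and 27.3% of the rises were on array 1. The rule left out genes whose other arrays lay further apart, such as myo-3 at 9.52, 10.90 and 10.24 on arrays 2 to 4. The share on array 1 therefore cannot decide whether age added to the rises there. A defect of single array features may be the source: the 8 other transcripts of 5 of these genes did not rise on the same array, with a median of -0.25 (-1.55 to 0.07), though so few cannot speak for all 44.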
